A study of Arabidopsis thaliana with 12 samples.

How the data were processed

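Gene expression in root tips was measured with one-colour Affymetrix ATH1 arrays, 12 in all, from 4 groups of 3 biological replicates. Per the labels, 250 ng of total RNA was labelled with biotin for each array. The deposited values are on a log2 scale, and per the submitters' processing notes they were made with Affymetrix Expression Console and RMA (the robust multi-array average), with limma named as well, the versions not being given in the sources used here. RMA corrects background, aligns the arrays' distributions and summarises the probes of a probe set, which pulls low signals together and understates changes of dim genes. The values were used as deposited.

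Of 22810 probe sets, 64 controls were left out and 22746 were tested. The platform annotation gave 13513 probe sets a single gene symbol, 503 several and 8730 none. Names were set beside a RefSeq gene table of assembly TAIR10.1, in which 13436 were found. No coordinates are given, since the arrays' values carry no genome build. Symbols of their own were rarer among named genes: 14.6% of genes with a symbol and 63.1% of genes known by locus tag had a named probe set, so many well-studied genes are not analysed here by name.

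Each comparison was a contrast in 1 linear model over all 12 arrays, fitted with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation and Benjamini-Hochberg adjustment over the tested probe sets, and a threshold of 0.05 on the adjusted p. A fold is a difference of mean log2 values. The groups, the tests, 27 gene lists and the rule for naming genes were set before the data were examined. The rule names every measured HD-ZIP III gene, the 6 largest rises and falls past the threshold with all induced arrays beyond the mock range, up to 4 members of each list past the threshold and otherwise up to 2 with the smallest p, 3 in each direction between later times, and the 5 highest F. Lists with at least 3 measured members, 8 of the 27, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Ribosomal proteins, to be found by symbol, matched no named gene. A further 24 families were added after the annotation was known, and the class III peroxidases only after peroxidases had been seen among the calls, so genes named from these families fall outside the rule and were chosen after their values were seen.

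The method was tested on simulated data with the real means and limma's moderated spreads. Noise was drawn independently for each probe set, unlike on the arrays, so error rates in the real data may differ. Of 67 probe sets changed by 0.5 at 10 h against 0 h, 64.2% were recovered, and of 67 changed by 1 all were, with 5 false calls among the 22746, against 8 at 6 h and 13 at 24 h. The alternatives tried were other scalings, a filter on dim probe sets, other variance moderation, array weights, the replicate number as a block, subsets of the arrays, a fold minimum and leaving out each array in turn. Per array, hybridisation spikes averaged 10.3 on mock replicate 1 and 9.32 to 9.78 on the others. The 3' to 5' difference of actin was 2.60 ± 0.14 (SD) at 0 h and 2.69 ± 0.11 (SD) at 10 h, with an exact permutation p = 0.4.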

Results

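Root tips of 0.5 mm were taken from Arabidopsis thaliana seedlings at 4 days post germination. The seedlings carried a transgene labelled with the CRE1 promoter, XVE and the microRNA precursor MIR165A. XVE is a transcription factor activated by ß-estradiol, which here serves to induce MIR165A. The CRE1 promoter is active in the stele, the central vascular cylinder of the root. MiR165 directs the cleavage of transcripts of the class III HD-ZIP transcription factors, which pattern the vascular tissue. There were 4 groups of 3 arrays each, with about 200 tips behind every array: seedlings on mock plates (called 0 h) and seedlings kept on 5 µM ß-estradiol for 6 h, 10 h or 24 h. The labels name the 3 samples of a group as biological replicates. Their number limits the precision. The design holds no estradiol-treated seedlings without the transgene, and its only mock group is labelled 0 h. Each comparison with 0 h thus measures induction together with the estradiol plate and the time spent on it. The arrays' medians ranged from 5.97 to 6.13 on the log2 scale. Pairs of arrays within a group correlated at 0.993 to 0.998, and pairs across groups at 0.990 to 0.997. The median SD between arrays of a group was 0.119 at 0 h, 0.101 at 6 h, 0.0952 at 10 h and 0.122 at 24 h.

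**Figure D1:**
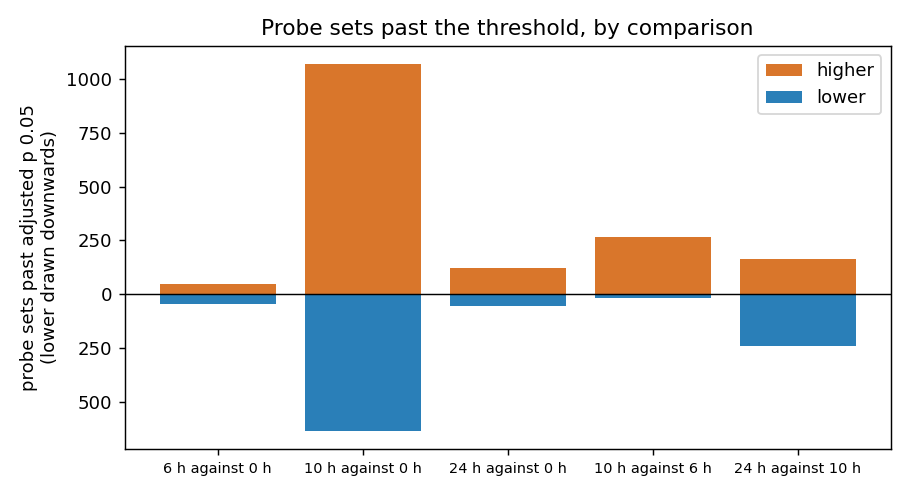
Number of probe sets past adjusted p 0.05 in each comparison (vertical axis, count), with higher probe sets drawn upwards and lower ones downwards. The 10 h against 0 h comparison holds 1070 higher and 635 lower probe sets, against 49 and 47 at 6 h.

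PHV, a class III HD-ZIP gene targeted by miR165, was the 1 member of that family with a named probe set, so the other members are not analysed here. Its mean log2 signal was 7.05 at 0 h, 6.74 at 6 h, 6.53 at 10 h and 6.64 at 24 h. At 10 h PHV fell by 0.52 (SE 0.10, limma adjusted p = 0.00631), less than the 1.5-fold minimum tried as an alternative for the counts. At 6 h the difference was -0.31 (limma adjusted p = 0.28) and at 24 h it was -0.41 (limma adjusted p = 0.0884), neither past the threshold. In each comparison the 3 induced arrays lay below the 3 mock arrays, whose lowest value was 6.99. An exact two-sided permutation test of PHV gave p = 0.1 each time, which is the smallest that 3 arrays against 3 allow. Adjusted over the list alone, which here is a single gene, PHV passed at 6 h, 10 h and 24 h. The mock arrays lay between 6.99 and 7.16, the 6 h arrays read 6.70, 6.80 and 6.70, the 10 h arrays 6.43, 6.47 and 6.68, and the 24 h arrays 6.74, 6.74 and 6.44.

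**Figure D2:**
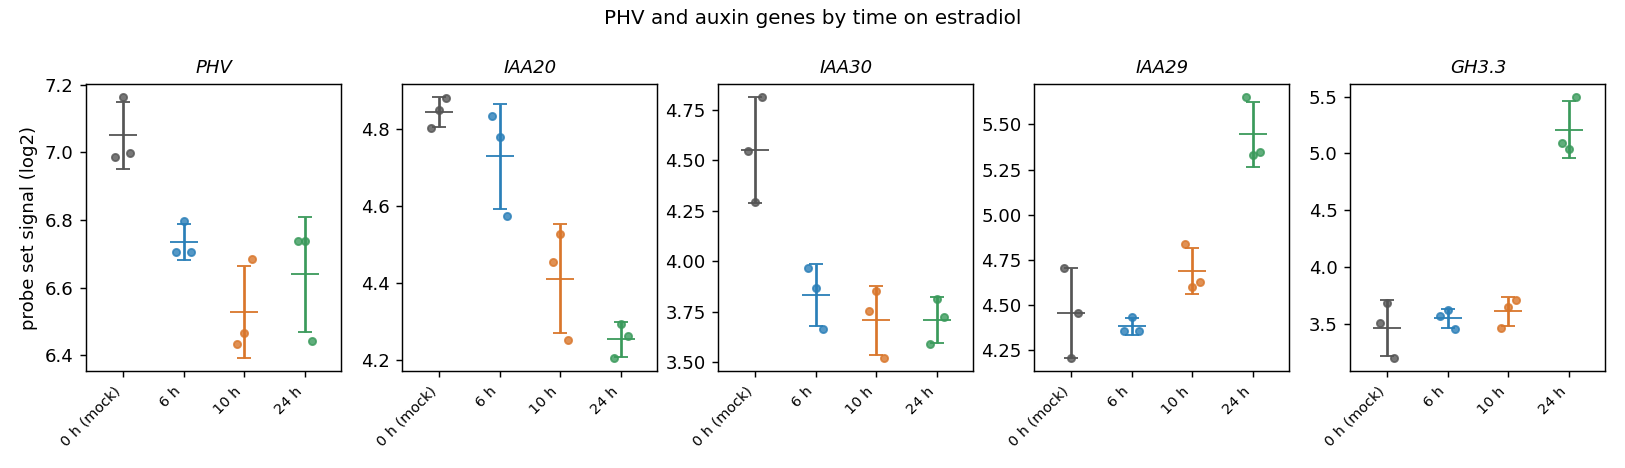
Probe set signal (log2, vertical axis) of PHV, IAA20, IAA30, IAA29 and GH3.3 by time on estradiol (horizontal axis). Points are arrays, and the horizontal dash with bars is the mean ± SD of 3 arrays. PHV lies lower in all induced arrays than in all mock arrays, and GH3.3 lies near 3.46 to 3.61 until 10 h and at 5.21 at 24 h.

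At 6 h against 0 h, 96 of 22746 probe sets passed, 49 higher and 47 lower, 55 of them with a gene name. The largest named rise was AT1G13930, by 2.17 (SE 0.16, limma adjusted p = 1.66e-05), and the largest named fall was AT5G04120, by -2.31 (SE 0.33, limma adjusted p = 0.00475). LCR69, a defensin-like peptide gene, rose by 1.38, and AT5G57785 rose by 1.48. AT4G11190, a dirigent family gene, fell by 1.93, AT5G15950, an S-adenosylmethionine decarboxylase gene, fell by 1.26, AT1G23160 of the GH3 family fell by 1.36, the expansin-like gene EXLA2 fell by 1.08 and the cellulase gene GH9B6 fell by 1.02. AT1G56300 (1.13), AT5G40590 (1.72) and AT1G49030 (1.62) completed the 6 largest rises. The adjusted p of AT5G40590 rose to as much as 0.158 and that of AT1G49030 to 0.14 under the alternatives.

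Of the fixed lists at 6 h, 1 of 7 measured Aux/IAA genes passed: IAA30, which fell by 0.72 (SE 0.13, limma adjusted p = 0.0262). In the epidermis and root hair list TRY, a MYB-related gene of epidermal patterning, fell by 0.57 (limma adjusted p = 0.0191). In the hypoxia and ethanol list PDC2, a pyruvate decarboxylase, rose by 0.88 (limma adjusted p = 0.0191). The clock gene GI read 0.39 higher (limma adjusted p = 0.0975), not past the threshold over all genes, and passed adjusted over the list alone, as the single measured member of its list, and so did the dehydrin COR47 (0.31, limma adjusted p = 0.427 over all genes). No list of the 8 that could be tested passed camera at 6 h, the smallest adjusted p being 0.4. Of the 24 added families the autophagy genes passed in the higher direction (camera adjusted p = 0.0454, and adjusted p = 0.846 with an estimated correlation), with 0 of 8 members past the threshold in limma. By unadjusted p under 0.05, 2135 probe sets differed in this comparison. Without mock replicate 1 there were 49 calls, without mock replicate 2 there were 41, without 6 h replicate 2 there were 34 and without 6 h replicate 3 there were 49. The calls on IAA30, TRY and PDC2 each ended without mock replicate 1, among other arrays.

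At 10 h against 0 h, 1705 probe sets passed, 1070 higher and 635 lower. The higher share was 62.8%, and 52.9% when each array was centred on its median. AT1G30870, a class III peroxidase gene, rose by 2.84 (SE 0.28, limma adjusted p = 7.56e-05). The root hair expansins EXPA7 and EXPA18 rose by 2.02 (SE 0.26) and 1.26 (SE 0.20), with limma adjusted p = 0.0004 and limma adjusted p = 0.00186. AT3G49960 and AT4G26010, also class III peroxidase genes, rose by 2.15 and 1.85. XTH18, a xyloglucan endotransglucosylase, rose by 1.34 and RALFL27, a RALF signal peptide, by 1.61. The cellulase GH9C1 rose to a mean of 5.91 from 3.91. AT1G13930 rose by 3.04 (SE 0.16, limma adjusted p = 3.29e-07). The other large named rises were AT3G23090 (2.42), AT2G23910 (2.39), AT5G57785 (2.34) and AT2G47540 (2.26).

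The largest named falls at 10 h were AT1G23160 (-1.58), AT4G11190 (-1.49), AT5G15950 (-1.38), AT5G04120 (-1.32), AT3G22060 (-1.16) and AT5G18840 (-1.14). AT5G04120 was no longer past the threshold without any 1 of the 3 mock or 3 induced arrays.

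Within the fixed lists at 10 h, 3 of the 7 Aux/IAA genes passed, and 4 adjusted over the list alone. IAA30 fell by 0.84 (limma adjusted p = 0.00161) and IAA20 by 0.43 (limma adjusted p = 0.011), while IAA18 rose by 0.44 (limma adjusted p = 0.0154). In the epidermis and root hair list all 3 measured genes passed, with TRY falling by 0.71 beside the rises of EXPA7 and EXPA18, and the list did not pass camera (adjusted p = 0.215). The cell elongation and differentiation list of 4 genes was the 1 list past camera (adjusted p = 0.0199), though adjusted p = 0.123 with an estimated correlation. XTH18 was its 1 member past the threshold. GSO1, a receptor kinase of the endodermal barrier, rose by 0.75, UPB1, a bHLH factor that regulates peroxidase genes, rose by 0.79, PDC2 rose by 0.77, the dehydrin COR47 rose by 0.72, WRKY53 rose by 0.92, GI rose by 0.40 and AT5G66390, a peroxidase gene of the secondary wall list, rose by 0.90. Neither PRL (-0.29) nor ICU2 (-0.27) of the S phase list and neither AUR3 (-0.25) nor AUR1 (-0.11) of the G2/M list passed over all genes, while 1 of the 2 S phase genes passed adjusted over the list alone.

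Of 55 measured class III peroxidase genes, a list drawn up after peroxidases had been seen among the leading calls, 14 rose and 2 fell at 10 h (camera adjusted p = 1.13e-06, and adjusted p = 0.282 with an estimated correlation). Families were also picked by symbol once the annotation was known and before any test. Of 22 trichome birefringence-like genes, which encode wall polysaccharide acetyltransferases, 5 rose and 1 fell (camera adjusted p = 0.0242, and adjusted p = 0.29 with an estimated correlation). TBL38 rose by 1.78, TBL21 by 1.56 and TBL19 by 1.01, while TBL36 fell by 0.74. Of 10 RALF-like genes 3 rose (camera adjusted p = 0.0413, and adjusted p = 0.29 with an estimated correlation), and of 9 XTH genes 2 rose (camera adjusted p = 0.019, and adjusted p = 0.29 with an estimated correlation). UGT84A1, a glucosyltransferase gene, rose by 2.04. EXPA7, EXPA18 and the 14 class III peroxidase genes that rose at 10 h, 16 in all, averaged 6.54, 6.54 and 6.85 on the mock arrays, 7.97, 7.99 and 8.21 at 10 h, and 6.85, 7.09 and 7.64 at 24 h. At 6 h their averages lay between 6.66 and 7.16. The 10 h count was 875 without 10 h replicate 3, 1042 without 10 h replicate 1, 1045 without 10 h replicate 2 and 980 without mock replicate 1, and 706 with a 1.5-fold minimum. The elongation list no longer passed without mock replicate 2, and the calls on IAA18, GSO1, UPB1, GI, WRKY53 and AT5G66390 each ended without at least 1 of the arrays compared, as did that on IAA20 without 10 h replicate 3.

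**Figure D3:**
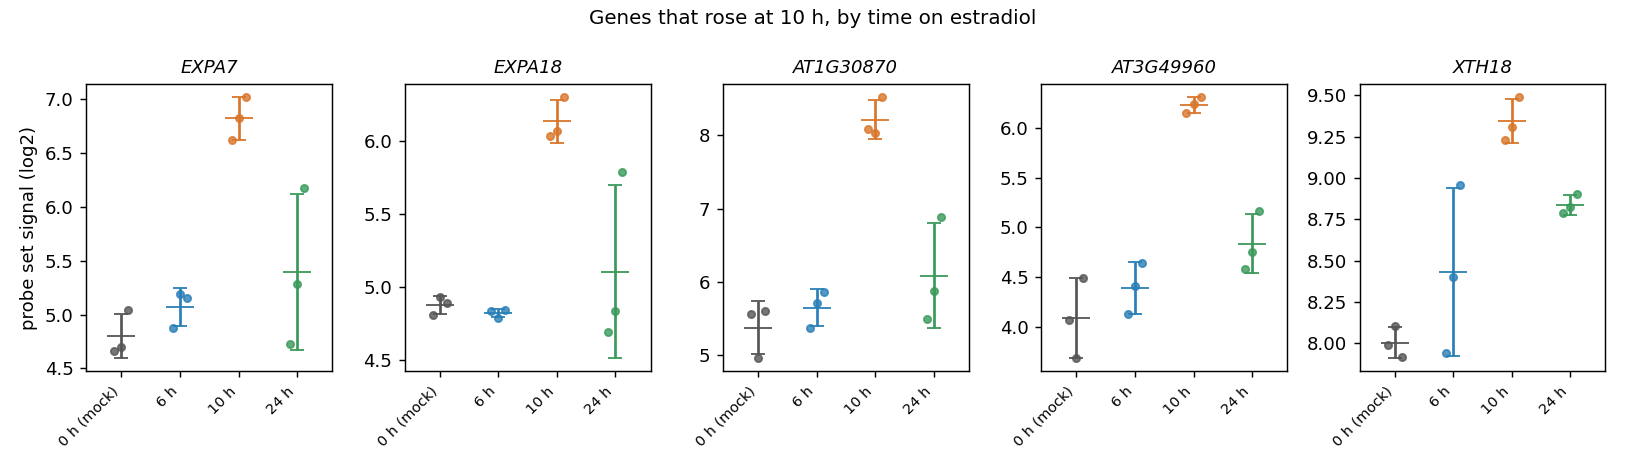
Probe set signal (log2, vertical axis) of EXPA7, EXPA18, AT1G30870, AT3G49960 and XTH18 by time on estradiol (horizontal axis), with each array as a point and the mean ± SD of 3 arrays as a dash with bars. EXPA7 averaged 4.80 at 0 h, 6.82 at 10 h and 5.39 at 24 h.

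**Figure D4:**
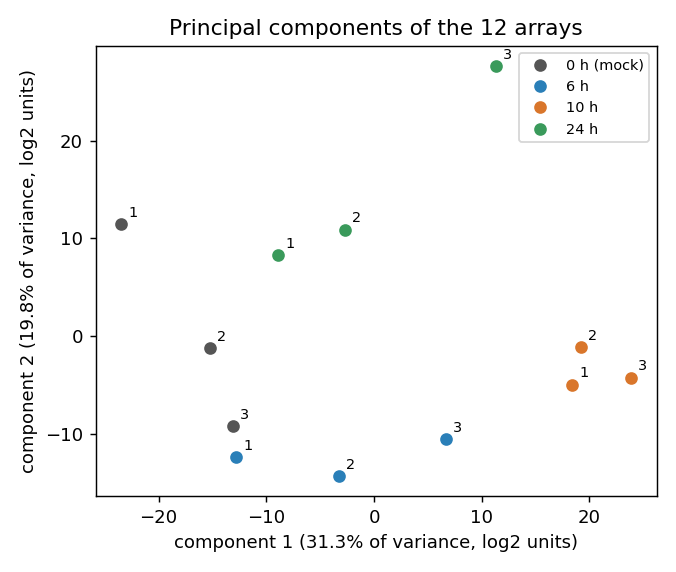
Arrays placed on the first principal components of all 22746 probe sets (log2 units), numbered by replicate and coloured by time. The 10 h arrays lie between 18.4 and 23.9 on component 1, the mock arrays between -23.5 and -13.1, and 24 h replicate 3 lies at 11.3.

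At 24 h against 0 h, 173 probe sets passed, 120 higher and 53 lower, 83 of them named. The auxin conjugating enzyme gene GH3.3 rose by 1.75 (SE 0.14, limma adjusted p = 1.73e-05). Among the Aux/IAA genes IAA29 rose by 0.99 (SE 0.12, limma adjusted p = 0.00116), IAA30 fell by 0.84 (SE 0.13, limma adjusted p = 0.0082) and IAA20 fell by 0.59 (SE 0.09, limma adjusted p = 0.00842). Among named genes AT3G27200 rose most, by 2.01 (limma adjusted p = 0.000158), and AT2G28410 fell most, by 1.91 (limma adjusted p = 7.29e-08). AT2G27740 rose by 1.46, AT5G12050 by 1.34, AT5G57785 by 1.65 and AT2G23910 by 1.61. AT3G10080 fell by 1.33, AT5G25490 by 1.31, AT3G42800 by 1.27, SAH7 by 1.14 and TBL36 by 1.06.

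Adjusted over the list alone, 5 of 7 Aux/IAA genes and 2 of 6 auxin response genes passed at 24 h. Members of the Aux/IAA list moved both ways, and camera did not pass (adjusted p = 0.0854). In the auxin response list the median was -0.03 and the mean 0.31, and camera gave adjusted p = 0.113. The peroxidase AT4G16270 rose by 0.96 and AT2G22420 fell by 0.54. TRY (-0.48) and XTH18 (0.84) passed by a narrow margin, with limma adjusted p = 0.0359 and limma adjusted p = 0.048. None of the 8 fixed lists passed camera at 24 h, and by unadjusted p under 0.05 there were 2441 probe sets. Of the 24 families 6 passed camera. The 69 plastid genome probe sets passed in the lower direction (adjusted p = 1.88e-07, median -0.20, 1 member past the threshold), and did not pass with an estimated correlation (adjusted p = 0.359). The class III peroxidases (adjusted p = 0.000544), the UDP-glycosyltransferases (adjusted p = 0.00519), the tau glutathione transferases (adjusted p = 0.00533), the trichome birefringence-like genes (adjusted p = 0.0358) and the expansins (adjusted p = 0.0441) passed in the higher direction, with few or no members past the threshold. With an estimated correlation none of the 24 passed, the smallest adjusted p being 0.301. Without 24 h replicate 3 the trichome birefringence-like genes (adjusted p = 0.13) and the expansins (adjusted p = 0.0836) no longer passed, nor did they without mock replicate 2 and at least 1 other array each, in a check added after the data were seen. On the 24 h arrays EXPA7 read 4.73, 5.29 and 6.17 and EXPA18 4.69, 4.84 and 5.79. The 24 h count was 65 without mock replicate 2, 94 without mock replicate 3 and 70 without 24 h replicate 2, and 53 with the arrays of the 2 groups alone, where IAA30 was no longer called (limma adjusted p = 0.0595, against 0.0082 here). Without 24 h replicate 3, 3 fixed lists passed, and the calls on TRY and XTH18 ended without any 1 mock array.

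**Figure D5:**
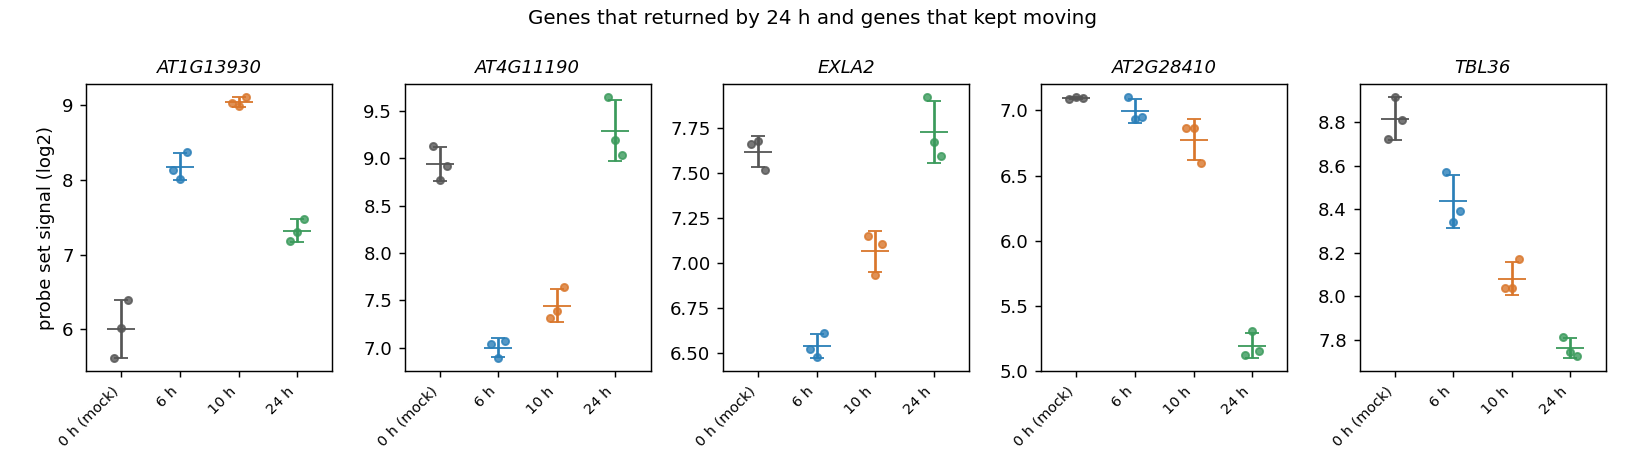
Probe set signal (log2, vertical axis) of AT1G13930, AT4G11190, EXLA2, AT2G28410 and TBL36 by time on estradiol (horizontal axis), with each array as a point and the mean ± SD of 3 arrays as a dash with bars. AT4G11190 averaged 8.93 at 0 h, 7.44 at 10 h and 9.29 at 24 h, and TBL36 averaged 8.82 at 0 h and 7.76 at 24 h.

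Between 6 h and 10 h, 267 probe sets rose and 16 fell. The largest named rises were AT1G30870 (2.57), AT3G23090 (2.13) and AT1G19900 (1.97), and the named falls AT1G76640 (-0.53), AT4G01790 (-0.52) and AT5G55210 (-0.44) were smaller. The epidermis and root hair list passed camera (adjusted p = 0.00133), with adjusted p = 0.112 with an estimated correlation, and EXPA7 and EXPA18 were its members past the threshold. The elongation list passed as well (adjusted p = 0.00133, and adjusted p = 0.0465 with an estimated correlation). Of the 24 families 10 passed camera, all in the higher direction, and 2 of these, the expansins and the GH9 cellulases, also passed with an estimated correlation (adjusted p = 0.0453 for both). The count of 283 fell to 64 without 10 h replicate 3, 96 without 10 h replicate 1, 184 without 10 h replicate 2, 86 without 6 h replicate 1 and 89 without 6 h replicate 2, and it was 433 without 6 h replicate 3.

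Between 10 h and 24 h, 165 probe sets rose and 242 fell. AT4G11190 (1.85), AT5G15950 (1.82) and GH3.3 (1.60) rose most among named genes, and AT1G30870 (-2.13), AT1G13930 (-1.73) and AT4G26010 (-1.70) fell most. The plastid genome, autophagy and class III peroxidase families passed camera in the lower direction (adjusted p = 0.00382 each), and none of the 24 passed with an estimated correlation (smallest adjusted p = 0.5). When each array was centred on its median the higher share of calls moved from 40.5% to 53.0%. The count of 407 was 93 without 10 h replicate 3, 129 without 10 h replicate 1, 146 without 24 h replicate 2, 235 without 24 h replicate 1 and 799 without 24 h replicate 3, and it fell without 10 h replicate 2 too.

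Over all times 1353 probe sets passed the F test, led among named genes by AT2G28410 (F = 187, adjusted p = 1.09e-07), AT1G13930 (F = 135), AT4G11190 (F = 119), GH3.3 (F = 75.5) and EXLA2 (F = 62.2). There were 638 without 10 h replicate 3, 706 without 10 h replicate 1, 798 without 10 h replicate 2 and 867 without 6 h replicate 2. The 6 h and 24 h calls shared 15 probe sets in the same direction, 7 higher and 8 lower, where independent lists would share 0.368. A further 1 was called in opposite directions. Simulated groups without any change shared 0 on average, but they held nothing to call, so this does not measure what shared controls add. Over all genes the 2 changes correlated at r = 0.327. A shared control alone gave 0.500 in the simulation, which held no real changes. Real changes add variance and can lower r, so these 2 values cannot be compared. The covariance of the 2 changes was 0.00989, against a mean of 0.00674 in the simulation. With 3 mock arrays the controls could not be split, so part of the excess of shared calls may come from sharing them. The count shared by 6 h and 24 h was 7 without mock replicate 2, 5 without 6 h replicate 2 and 25 without 24 h replicate 3. The 10 h and 24 h calls shared 116 in the same direction, 67.1% of the 24 h calls, where independent lists would share 7.12. The 6 h and 10 h calls shared 86, 89.6% of the 6 h calls, where independent lists would share 3.62. These overlaps share the mock arrays too.

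Several other fixed lists had only 1 or 2 measured genes each, and these did not pass over all genes at any time: HAT2 of HD-ZIP II, AGO7 and SE of the small-RNA list, YUC2 and YUC6 of auxin synthesis, ARR15 and RR16 of the cytokinin list, the phloem gene OPS (0.33 at 24 h, limma adjusted p = 0.103, past adjusted over its list of 1 gene), the stele gene MOL1, and EIN3 and RTE1 of the ethylene list. Some fixed lists had no measured gene at all, so nothing can be said of their members. They were the LITTLE ZIPPER (ZPR) genes transcribed under HD-ZIP III control, xylem identity and thermospermine, root cap, and nitrate and phosphate.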

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

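All of the tests of explanations in this part were chosen after the results they address had been seen. The values here are differences between successive times on the log2 scale, each past limma's adjusted p of 0.05 in the contrast itself, for genes called against 0 h. They mark genes whose change from 0 h was not the same at both times.

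Between 10 h and 24 h some of the genes called at 6 h or 10 h turned back towards their 0 h level, and those given here were taken because they passed in that contrast. AT1G13930 changed by -1.73, AT1G56300 by -1.08, RALFL32 by -0.48, WRKY53 by -1.12 and COR47 by -0.54, and the falls of AT4G11190 (1.85), AT1G23160 (0.72), AT5G15950 (1.82), EXLA2 (0.67), AT3G22060 (0.64) and AT5G18840 (0.90) were partly or fully undone. Before that, from 6 h to 10 h, AT1G13930 had changed by 0.87, AT5G57785 by 0.86 and EXLA2 by 0.53.

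Some genes made most of their change between 10 h and 24 h: GH3.3 by 1.60, IAA29 by 0.76, AT2G28410 by -1.58, AT3G10080 by -1.40 and SAH7 by -1.05. AT2G27740 (0.78) and AT5G25490 (-0.57) had been called at 10 h and moved further the same way. AT3G27200 had changed by 1.22 and AT5G12050 by 1.02 between 6 h and 10 h.

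From 6 h to 10 h the following genes, each taken because it passed, rose. The class III peroxidases, expansins and other genes of wall or peptide families were AT1G30870 by 2.57, AT3G49960 by 1.84, AT4G26010 by 1.68, AT5G66390 by 1.08, AT4G16270 by 0.63, EXPA7 by 1.75, EXPA18 by 1.31, EXPB1 by 0.50, XTH18 by 0.91, GH9C1 by 1.91, RALFL27 by 1.02, TBL19 by 0.59, TBL21 by 1.09 and TBL38 by 1.34. Of other kinds or not assigned were GSTU28 by 1.46, UGT84A1 by 1.45, CYP71B34 by 0.64, AT3G23090 by 2.13 and AT2G47540 by 1.59. From 10 h to 24 h AT1G30870 changed by -2.13, AT3G49960 by -1.40, AT4G26010 by -1.70, EXPA7 by -1.43, EXPA18 by -1.03, TBL19 by -0.61 and CYP71B34 by -0.46.

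The rise of EXPA7, EXPA18 and class III peroxidase genes at 10 h has several candidate explanations. For a response to induction that keeps its size, genes were chosen on the other replicates from a pool of EXPA7, EXPA18 and the class III peroxidases. The peroxidases had entered this pool after some had been seen among the calls on all arrays, so the held-out rise is not fully independent. At most 44.6% of the held-out 10 h rise then remained in the 24 h mean. That mean was the same in every run, and on its arrays EXPA7 read 4.73, 5.29 and 6.17. Since the share of differentiated tissue may also differ between dissections, these values do not decide the question. A share of more differentiated tissue that varies between dissections stays open. Over the 1705 probe sets called at 10 h the change correlated with the difference between 2 arrays of the same group. The median absolute r was 0.511 over 6 pairs, some of which share an array, against 0.256 over all probe sets. The 1705 were chosen for their change at 10 h, and genes are not independent. In all 6 pairs r was positive with the higher replicate number first (0.368 to 0.639), so the difference also followed replicate number. This test replaced a first version, on 1 pair of 6 h arrays chosen from the principal components, after the value of that version had been seen, and its cutoff was set then too. Time of day cannot be told apart, because GI is the single measured gene of the fixed clock list (0.40 at 10 h), and the clock-linked genes COR27 (0.59) and AT4G33980 (0.69) were picked after their values were seen. A passing response to miR165, to estradiol or to the time on the plate was not tested.

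At 24 h IAA20, IAA30, IAA29 and GH3.3 each kept at least 84.3% of their change without any 1 array of the 2 groups. They had been called on these same arrays, which by itself favours a change spread over the arrays. Noise of dim probe sets was examined with the spread modelled on the signal, a fit under which 13 of 116 named calls ended. All 4 genes stayed past the threshold over all probe sets (highest limma adjusted p = 0.0112). The 4 genes had been chosen for their changes on these same arrays, so this fit cannot decide the question. It took the place of a first version that the choice of genes also made void, and its outcome was known when it was taken up. An effect of the estradiol plate itself, or of the time spent on it, stays open, as untested.

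Other splits of the arrays gave fewer calls than the real ones in each comparison, but 10 splits of 6 arrays are too few for a share under 0.05. The real split was 1 of the 10 with as many calls each time. At 6 h it gave 96 calls and the highest other 1, at 10 h 1705 and 0, at 24 h 173 and 20, from 6 h to 10 h 283 and 0, and from 10 h to 24 h 407 and 0. For fixed lists, at 6 h 10 of the 10 splits gave as many as the real 0 (highest other 0), at 10 h 1 split gave as many as the real 1 (highest other 0), and at 24 h 10 gave as many as the real 0 (highest other 1). For the F test 100 splits were compared, the real one included, and it alone reached 1353, the highest other being 40. That is the smallest share that 100 splits allow, so a random split seldom gives as many calls. For the probe sets shared by 6 h and 24 h, 4 of 100 reached the real 15, the real split being 1 of the 4. The highest other was 67, from a split that kept the 24 h arrays together as the control, and the other splits above 15 kept the 6 h arrays together in that place, which points to the arrays' own group structure.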

How the results depend on the processing

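The alternatives with the 10 h arrays left out, with 3 arrays left out together and with a root-hair index were chosen after seeing the data. The cause of the shifts was not tested except where fewer arrays or genes enter. Same-numbered arrays were not treated as pairs, because 8 of 18 such pairs had r above 0.1 where all were required, and no label says that a number marks a shared day. There are hints of a shared order: 8 of 12 arrays correlated better with their own number, and component 1 rose from replicate 1 to 3 in each of the 4 groups. With the replicate block the calls were 160 at 6 h, 355 at 24 h, 481 from 6 h to 10 h and 646 from 10 h to 24 h, with 43 shared by 6 h and 24 h, and no other count moved over 1.5 times. With the arrays of the 2 groups alone there were 53 at 24 h and 483 from 6 h to 10 h, 5 shared, and 2 lists at 10 h and 1 at 24 h. Cyclic loess gave 150 at 6 h and 2 lists at 24 h. Without dim probe sets 0 lists passed at 10 h, as with an estimated correlation (0), while fry gave 2 at 10 h and 3 at 24 h. Trend and robust moderation gave 169 at 6 h, 685 from 10 h to 24 h and 25 shared. Array weights gave 239 at 6 h, 520 at 24 h, 1351 from 6 h to 10 h, 2068 from 10 h to 24 h, 3593 at any time, 41 shared and 3 lists at 24 h. A 1.5-fold minimum left 706 at 10 h, 185 from 10 h to 24 h and 685 at any time.

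Without the 10 h arrays there were 52 calls at 6 h and 79 at 24 h. Without the 3 arrays that stand apart there were 294 at 24 h, 862 from 6 h to 10 h and 1226 from 10 h to 24 h. With the root-hair index (mean of EXPA7 and EXPA18) as a covariate there were 162 at 6 h and 133 at 10 h. The 10 h arrays all have a high index, so the covariate takes up most of the 10 h contrast by construction. Of the 1705 probe sets called at 10 h, 1469 kept their sign under it. Only 57 of the 133 called at 10 h with the index were among the 1705 in the same direction. Among named calls AT5G04120 read 0.71, AT5G66390 -0.19, GSO1 -0.069, EXPA18 (itself part of the index) -0.15, SCPL45 -0.095, GH9C1 -0.11, GH9B6 0.0038, GSTU28 -0.26, CML42 -0.10, CLE27 0.18 and ATG8E -0.14, each reversed. Leaving out 1 array gave 34 to 126 calls at 6 h, 875 to 1420 at 10 h, 65 to 190 at 24 h, 64 to 433 from 6 h to 10 h, 93 to 799 from 10 h to 24 h, 638 to 1753 at any time, 5 to 25 shared, 0 to 1 lists at 10 h and 0 to 3 at 24 h. The count of HD-ZIP III genes past the threshold, here PHV alone, stayed at 1 at 10 h and at 0 at 6 h and 24 h in the alternatives run for that count. These did not include the fold minimum, the 10 h arrays left out, the 3 arrays left out together or the root-hair index. The change of PHV at 10 h, -0.52, lies under the fold minimum of 0.58. Of 116 named calls, the replicate block kept 113, median centring 108, cyclic loess 112, array weights 116, trend and robust moderation 103 and the arrays of the 2 groups alone 100. Leaving out 1 array cost more: 72 of 104 stayed without mock replicate 1, 81 without mock replicate 2, 14 of 23 without 6 h replicate 2, 55 of 76 without 10 h replicate 3 and 22 of 29 without 24 h replicate 2. Without the 10 h arrays 27 of 40 stayed, without the 3 arrays that stand apart 105 of 116, and with the root-hair index 39 of 104. Signal near background limits dim genes, which RMA compresses.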

Other observations

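The tests in this part were chosen after the results were seen. Part of the probe sets that differed from 0 h at 6 h and 10 h lay nearer their 0 h level at 24 h. Of 86 probe sets called in the same direction at 6 h and at 10 h, 42 were called back towards 0 h from 10 h to 24 h, 1 was called further away and 15 were still called the same way against 0 h at 24 h. Both steps use the 10 h arrays, which by itself favours such a return. With 1 array of the 10 h group kept out of the choice and compared with the 24 h mean, 92.3% to 96.4% of 56 to 65 probe sets, which are not independent, had moved back. The array kept out shares any offset of the 10 h group, so this does not tell a reversal from such an offset. The cold and clock-linked genes COR27 (0.63 at 6 h, 0.59 at 10 h, 0.00073 at 24 h) and AT4G33980 (0.77, 0.69 and -0.04) were among the 42, as was the dehydrin LTI30 (1.09, 1.07 and 0.31), and these 3 were picked after their values were seen.

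Of the 173 probe sets called at 24 h, 58 (33.5%) had group means in the order of the times, and 9 had them in order with 6 h and 10 h exchanged. The calls themselves set the 2 ends of the order, and 10 h differed more from 0 h than 6 h did, so these counts do not show a steady course. Among the 58 were IAA20, TBL36 and AT3G42800 falling, and AT3G27200 and AT2G27740 rising.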
